A study of Mus musculus with 8 samples.

How the data were processed

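RNA was measured by sequencing in prefrontal cortex and hippocampus of 8-week-old wild-type and PTENδ knockout mice, 2 libraries per tissue and genotype, as per the labels. Per the labels RNA was extracted with Trizol, checked on a Bioanalyzer, made into libraries with the Illumina TruSeq RNA Sample Prep Kit and sequenced on an Illumina NovaSeq. The submitters' processing notes name CASAVA, HISAT2 2.0.5, featureCounts 1.5.0-p3 and the mm10 genome. The gene annotation release, the strand setting and any read filter are not given in the sources used here. Because the strand setting is not given, counts of overlapping antisense genes are uncertain. Counts of near-identical gene copies are uncertain because a read can fit several copies.

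The deposited count table holds an integer count of reads per gene and library for 32820 genes, per the file headers. The deposited FPKM columns, which are headed only by sample names, are read as counts scaled by gene length and by the library total. The deposited comparison of the authors, which sets the 4 knockout against the 4 wild-type libraries, holds a signal (the mean over all libraries of counts divided by size factors), a fold change ratio, its log2 value, a p-value and an adjusted p-value, per the file headers. The counts and FPKM values were checked against each other: in 12170 genes with at least 100 counts in 2 or more libraries, the length implied by the FPKM varied between those libraries by a relative spread of at most 3.36e-09. Libraries were matched to groups by the names in the labels, and 0 libraries were left out. The replicate numbers are only names and were not shown to pair libraries, so no block was used in the fit.

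Total counts ran from 17474093 to 18463933 per library, and the 10 most counted genes took 5.13% to 6.83% of them. The count table was filtered with filterByExpr of edgeR 4.0.16 (minimum count 10, minimum total 15), which kept 17990 genes. TMM factors ran from 0.991 to 1.01. A quasi-likelihood negative binomial model with 1 mean for each of the 4 groups was fitted to all 8 libraries, with a common dispersion of 0.00555, a biological coefficient of variation of 7.45% and 4 residual degrees of freedom. Between the 2 libraries of a group the chi-square per degree of freedom was 7.90 in wild-type PFC, 3.87 in knockout PFC, 5.35 in wild-type and 6.35 in knockout hippocampus, over genes with at least 20 counts in the pair.

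Contrasts were knockout against wild type in each tissue, their mean, their difference, and hippocampus against PFC in wild type. A gene was called at a Benjamini-Hochberg adjusted p-value under 0.05, and "rose" or "fell" is used for what passed. Pten is always named. Of the called genes with an average log2 CPM of at least 1 and no overlap of CPM between the groups, up to 12 in each direction with the largest fold change are named for the genotype contrasts, and up to 8 for the difference between tissues and for hippocampus against PFC. Where fewer than 10 passed, the 10 with the smallest p are named instead, called or not. Predicted genes, Rik symbols and pseudogenes are left out of the names. Up to 4 members of a list are named by p, with those that the count over the list alone needs. Gm10599, Gm10591, Ccl21b, the other genes of single libraries, Plp1, Mbp, Olig1, Olig2, Enpp2, Tbx21 and the cerebellar genes are outside this rule and were chosen after their values were seen. Values of groups are mean CPM ± SD with n = 2, scaled by the total of the tested genes times the TMM factor.

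The lists of genes by pathway, cell type and brain region, 42 in number, were fixed before the data were examined, and 41 were tested with camera of limma 3.58.1 (correlation between genes preset to 0.01). The remaining one, genes on the sex chromosomes, was planned to be read only per library. Adjusted p-values of lists cover the 41 lists of a comparison. Counts adjusted over the list alone apply the Benjamini-Hochberg step to the members of 1 list. A list score is the mean log2 CPM of the members around the mean of the tissue's 4 libraries. Coordinates are those of GENCODE M21 on mm10, in which 32069 of the 32820 gene identifiers were found.

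The comparisons, the fit, the naming rule and most alternatives were also written before the data were examined. Alternatives were RLE factors, library totals without TMM, no filter beyond a total count above 0, at least 10 counts in every library of at least 1 group, DESeq2 1.42.0, limma with a trend on log2 FPKM with 1 or 0.1 added, each tissue fitted alone, the replicate number as a block within tissue, libraries of 1 genotype and number taken as 1 animal, an adjusted p-value under 0.1, an absolute log2 fold change of at least 1, camera with an estimated correlation, fry, and each library left out in turn. A minimum average log2 CPM of 4 and a prior count of 5 were tried for the correlation across genes. A robust prior, tissue left out of the model, the alternatives on single lists and all alternatives for the lists that differ between tissues were added after the data were seen. The fit was tested on simulated data made from the mean of each tissue: at a log2 fold change of 1 it recovered 64% of 100 changed genes in PFC and 76% in hippocampus, and at 0.6 it recovered 60% and 51%. Of 17790 unchanged simulated genes, 14 were called in PFC and 18 in hippocampus. Beside the changed genes recovered, 64 and 60 in PFC and 76 and 51 in hippocampus, these false calls were a larger share than the threshold of 0.05 sets. Scripts ran in R 4.3.3 and Python 3.11.15 with matplotlib 3.10.9.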

Results

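The data are RNA-seq gene counts from prefrontal cortex (PFC) and hippocampus of 8-week-old wild-type and PTENδ knockout mice, with 2 libraries in each of the 4 groups. The libraries held 17601544 and 18320323 counted reads in wild-type PFC, 18232964 and 18150028 in knockout PFC, 18463933 and 17976297 in wild-type hippocampus and 17622790 and 17474093 in knockout hippocampus. Of 32820 genes in the count table, 17990 passed the expression filter and were tested in every comparison. Values are mean CPM (read counts of a gene scaled to the TMM-adjusted total of the tested genes) ± SD with n = 2 per group unless another n is given, and SE is the standard error of a log2 fold change. The labels do not say that the 2 libraries of a group come from separate animals, so the p-values measure only the spread between libraries.

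Pten (ENSMUSG00000013663, chromosome 19 from 32757497 to 32826160 in mm10), which encodes the lipid phosphatase that opposes PI3K signalling, was counted at similar levels in both genotypes. Its counts were 3534 and 3287 in wild-type PFC, 3550 and 3706 in knockout PFC, 2884 and 2721 in wild-type hippocampus, and 2825 and 2683 in knockout hippocampus. These are 192 ± 14.8 and 200.4 ± 7.10 CPM in PFC and 152 ± 3.79 and 157 ± 4.65 CPM in hippocampus, wild type and knockout in turn. The knockout to wild-type log2 fold change of Pten was 0.06 (SE 0.07, 95% confidence interval -0.08 to 0.21, adjusted p = 0.949) in PFC, 0.05 (SE 0.07, 95% confidence interval -0.10 to 0.20, adjusted p = 0.956) in hippocampus and 0.06 (SE 0.05, 95% confidence interval -0.05 to 0.16, adjusted p = 0.933) averaged over both tissues. Without wild-type PFC replicate 2 the PFC value was -0.0156. A gene-level count cannot show the loss of 1 protein form of PTEN, so these libraries do not test whether PTENδ itself is absent. Of the 65 tested genes within 5 Mb of Pten, edgeR called 0 in PFC, in hippocampus or averaged, and at unadjusted p under 0.05 the share was 4.62%, 3.08% and 6.15% against 5.83%, 5.98% and 5.78% of all genes.

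In the hippocampus, 5 genes of oligodendrocytes and their myelin fell in knockouts. Fa2h (ENSMUSG00000033579, chromosome 8 from 111345135 to 111393824), which makes the hydroxylated fatty acids of myelin lipids, went from 39.6 ± 0.948 to 24.2 ± 1.26 CPM (log2 fold change -0.71, SE 0.09, adjusted p = 0.0247). Mal (ENSMUSG00000027375, chromosome 2 from 127633226 to 127656695), a myelin membrane proteolipid, went from 310.2 ± 2.76 to 191 ± 1.05 CPM (log2 fold change -0.70, SE 0.10, adjusted p = 0.0431), and Mog (ENSMUSG00000076439, chromosome 17 from 37010743 to 37023398), a protein on the outer face of myelin, from 75.8 ± 0.768 to 45.4 ± 0.396 CPM (log2 fold change -0.74, SE 0.11, adjusted p = 0.0431). Trf (ENSMUSG00000032554, chromosome 9 from 103204001 to 103230444), the iron carrier transferrin, went from 249 ± 3.00 to 175 ± 8.77 CPM (log2 fold change -0.51, SE 0.06, adjusted p = 0.0247), and Ermn (ENSMUSG00000026830, chromosome 2 from 58045113 to 58052864), an oligodendrocyte cytoskeleton protein, from 59.3 ± 1.80 to 41.3 ± 3.76 CPM (log2 fold change -0.52, SE 0.08, adjusted p = 0.0466). Igfn1 (ENSMUSG00000051985, chromosome 1 from 135953578 to 136006342), which encodes an immunoglobulin-domain protein first studied in skeletal muscle, rose from 3.10 ± 0.434 to 10.1 ± 4.35 CPM (log2 fold change 1.71, SE 0.25, adjusted p = 0.0466).

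These 6 genes, 1 higher and 5 lower, were all that edgeR called of 17990 in hippocampus, where 1076 genes (5.98%) had unadjusted p under 0.05, DESeq2 called 18 and limma 0. The count was 0 without knockout hippocampus replicate 2, 1 (none of these 6) without wild-type replicate 2, 42 lower (Trf and Fa2h of these 6) without wild-type replicate 1, 11 without knockout PFC replicate 2, and 16 without wild-type PFC replicate 1 or replicate 2. Without knockout hippocampus replicate 1 it was 6 higher and 0 lower, with Igfn1 alone shared and the 5 myelin calls lost, at log2 fold changes of -0.46 for Trf, -0.66 for Fa2h, -0.69 for Mal, -0.73 for Mog and -0.43 for Ermn. Without wild-type hippocampus replicate 2 the log2 fold changes of Trf, Fa2h, Mal, Mog and Ermn were -0.50, -0.69, -0.71, -0.75 and -0.49. Without knockout hippocampus replicate 2 they were -0.56, -0.76, -0.69, -0.74 and -0.61. With all libraries the next genes by p were Cnp -0.65, Mobp -0.72, Aspa -0.66 and Tmem88b -0.52 on the log2 scale, with adjusted p of 0.0533, 0.0904, 0.1001 and 0.106.

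**Figure D1:**
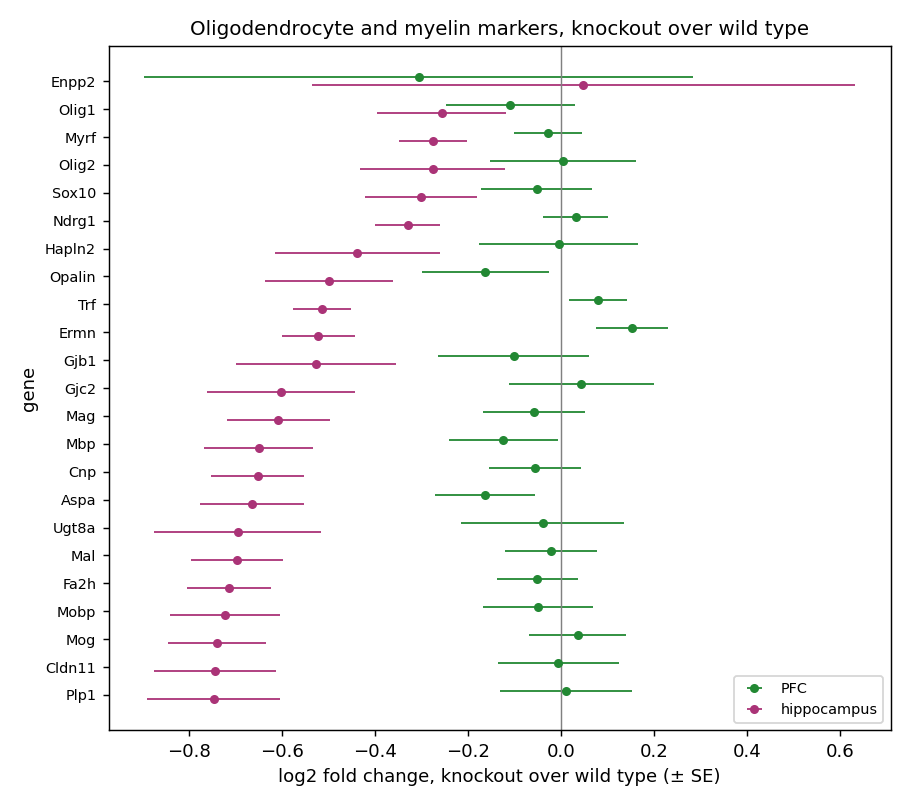
Log2 fold change (knockout over wild type, ± SE, 2 against 2 libraries) of each of the 23 measured oligodendrocyte and myelin markers, in PFC (green) and hippocampus (purple). The hippocampal median is -0.60 and the PFC median -0.04.

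The whole oligodendrocyte and myelin list fell in knockout hippocampus (median log2 fold change -0.60, adjusted p = 1.58e-68, adjusted p = 0.0722 with an estimated correlation). Of its genes 22 of 23 were below 0, with 5 called over all genes and 20 fallen when adjusted over the list alone. Plp1, the main proteolipid of central myelin, was -0.75, SE 0.14 on the log2 scale (2077 ± 0.149 to 1238 ± 54.7 CPM). Mbp, the myelin basic protein that compacts the sheath, was -0.65, SE 0.12 (2644 ± 236 to 1685 ± 31.1 CPM). The 3 that did not pass over the list alone were the lineage transcription factors Olig1 (-0.26) and Olig2 (-0.28) and Enpp2 (0.05, SE 0.58), an enzyme also made by the choroid plexus. Enpp2 turned to -0.61 without wild-type hippocampus replicate 2, to -1.62 without knockout replicate 1, to -0.10 with the replicate block, and to -0.13 and -0.14 by limma. The list score, a mean log2 CPM around the tissue mean, was 0.28 and 0.25 in wild-type and -0.25 and -0.29 in knockout hippocampus. Wild-type hippocampus replicate 2 also carried cerebellar transcripts, among them Cbln3 at 1517 counts against 18 or fewer in each other library, and without that library 18 of the 23 fell over the list alone.

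Other glial lists were lower too. Astrocyte markers (median log2 fold change -0.18, adjusted p = 1.61e-06, adjusted p = 0.630 with an estimated correlation) included Slc4a4 at -0.21 and Mlc1 at -0.18, both membrane proteins of astrocyte end feet. Ependymal and cilia markers (-0.42, adjusted p = 1.94e-05, adjusted p = 0.490 with an estimated correlation) included Tmem212 at -1.58 and Ccdc153 at -0.80. Oligodendrocyte precursor markers were also lower (-0.15, adjusted p = 0.0135, adjusted p = 0.630 with an estimated correlation). Wild-type replicate 1, wild-type replicate 2 (the library with cerebellar transcripts) and the 2 knockouts had scores of 0.03, 0.14, -0.08 and -0.10 for astrocyte markers. In the same order the ependymal scores were 0.32, 0.20, 0.00 and -0.52, the lowest in knockout replicate 2. Neurogenesis and proliferation markers were lower (-0.14, adjusted p = 3.51e-04, adjusted p = 0.351 with an estimated correlation). Of these, the calcium-binding protein Calb2 was -0.65 and the granule neuron factor Neurod1 -0.54, 2 genes also expressed in cerebellum. The neurogenesis score was 0.08 and 0.10 in wild type and 0.01 in knockout replicate 1, with replicate 2 apart at -0.19.

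Glucocorticoid-responsive genes were lower (-0.16, adjusted p = 0.00736, adjusted p = 0.490 with an estimated correlation), with the kinase gene Sgk1 at -0.35 and Arrdc2 at -0.29. So were cholesterol synthesis genes (-0.11, adjusted p = 0.0288, adjusted p = 0.560 with an estimated correlation). Ribosomal protein genes had a median of -0.05, adjusted p = 0.0152, adjusted p = 0.758 with an estimated correlation. Hypothalamic and pituitary markers were lower (-0.24, adjusted p = 0.0322, adjusted p = 0.630 with an estimated correlation). In that list 2 fell when adjusted over the list alone, the releasing-hormone gene Trh at -3.64, SE 1.03 (2.93 ± 3.77 to 0.229 ± 0.163 CPM), and the imprinted gene Peg10 at -0.41, SE 0.12. The list score was 0.45 in wild-type replicate 2, the library with cerebellar transcripts, against -0.08 in wild-type replicate 1, and 0.02 and -0.39 in knockouts.

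In knockout hippocampus 6 lists stood slightly higher. Immediate early genes, switched on by neuronal activity, had a median of 0.14, adjusted p = 0.00237, adjusted p = 0.630 with an estimated correlation. The zinc-finger factors Egr3 and Egr4 were 0.26 and 0.39. Their list score overlapped between genotypes, with -0.21 and 0.07 in wild type and 0.18 and -0.05 in knockouts. Presynaptic release genes were higher (0.09, adjusted p = 0.00736, adjusted p = 0.630 with an estimated correlation). The vesicle priming factor Unc13a was 0.21 and the membrane syntaxin Stx1a 0.38, while Unc13c, a priming factor of cerebellar granule cells, was -0.55. The presynaptic score overlapped between genotypes, with -0.04 and 0.00 in wild type and -0.01 and 0.05 in knockouts, the highest in knockout replicate 2. Cortical projection neuron markers were higher (0.11, adjusted p = 0.00824, adjusted p = 0.490 with an estimated correlation). Of these, 2 rose over the list alone, Coch at 0.50, SE 0.13 and Otof at 0.85, SE 0.24. Their list score was -0.14 and 0.03 in wild type and -0.03 and 0.15 in knockouts, and the highest was in knockout replicate 2, where the 49 genes enriched in PFC had a median of 0.35.

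The list of voltage-gated sodium and potassium channels, which also holds calcium channel genes, was higher (0.07, adjusted p = 0.00824, adjusted p = 0.630 with an estimated correlation). Glutamate receptors and excitatory synapse genes had a median of 0.07, adjusted p = 0.0135, adjusted p = 0.351 with an estimated correlation. CA1 and CA3 pyramidal markers had one of 0.07, adjusted p = 0.0318, adjusted p = 0.630 with an estimated correlation, with overlapping scores of 0.00 and -0.05 in wild type and 0.08 and -0.03 in knockouts. The other 26 of the 41 lists were not called (adjusted p from 0.0753 to 0.930, medians from -0.20 to 0.33). Among them were the PI3K-AKT-mTOR pathway genes (median 0.00), FoxO target genes (-0.03) and microglia markers (-0.09).

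Of the 15 lists that camera called in hippocampus, 6 higher and 9 lower, 0 held with an estimated correlation between genes. By fry, which asks whether the genes of a set move on balance in one direction and does not compare them with other genes, 0 were called. Outside the oligodendrocyte list 0 members of the called lists passed over all genes, and adjusted over the list alone 0 passed beyond the 4 given for the cortical and hypothalamic lists.

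In the PFC, markers of striatal neurons stood higher in knockouts and no single gene was called. Gpr6, an orphan receptor of striatal projection neurons, was 1.16, SE 0.25 on the log2 scale. Adcy5, the adenylyl cyclase behind striatal dopamine signalling, was 0.65, SE 0.17, and Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP, was 0.78, SE 0.21. All 21 measured striatal genes were above 0 (median log2 fold change 0.81, adjusted p = 1.17e-34, adjusted p = 0.425 with an estimated correlation). Of them 20 rose when adjusted over the list alone and 0 over all genes. Wild-type PFC replicate 1 stood apart, with a striatal score of -1.09 against 0.14 in wild-type replicate 2 and 0.37 and 0.57 in knockouts. Over the list alone the count was 9 without that library (median 0.32) and 0 without knockout PFC replicate 2 (median 0.74).

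The list of olfactory bulb and migrating neuroblast markers also rose in knockout PFC (median log2 fold change 0.50, adjusted p = 1.18e-16, adjusted p = 0.0327 with an estimated correlation). Members with little change included Dcx at 0.06, Dlx1 at 0.01, Dlx2 at -0.11, Etv1 at 0.03 and Doc2g at -0.05. In the list 15 of 17 genes were above 0, with 0 called over all genes and 8 risen when adjusted over the list alone. The first of these 8 by p was Cdhr1 (ENSMUSG00000021803, chromosome 14 from 37077857 to 37098347), a cadherin of photoreceptors and olfactory bulb neurons, at 4.58 ± 1.71 to 13.4 ± 0.692 CPM (log2 fold change 1.54, SE 0.20, adjusted p = 0.0804 over all genes). The others named by p were Synpr, a synaptic vesicle protein, at 0.33, SE 0.07, the interneuron transcription factor Meis2 at 0.49, SE 0.11, and Calb2 at 0.92, SE 0.22. The olfactory bulb list was the only 1 of the 9 lists called in PFC that held with an estimated correlation. By fry 0 of the 41 lists were called. The largest fold changes in the olfactory bulb list were at low counts. They were Tbx21 at 3.68, SE 0.94 (0.0562 to 0.801 CPM) and Eomes at 2.34, SE 0.67 (0.171 to 0.883 CPM). A different share of olfactory bulb tissue between the PFC pieces was not tested. Camera called 17 lists without wild-type PFC replicate 1 and 14 without wild-type PFC replicate 2. The olfactory bulb scores were -0.31 and -0.14 in wild type and 0.15 and 0.29 in knockouts, the lowest of them in wild-type replicate 1, the library with the low striatal score. Without that library the median was 0.33 (SD 1.19 over 17 genes), with 1 wild-type PFC library left.

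**Figure D2:**
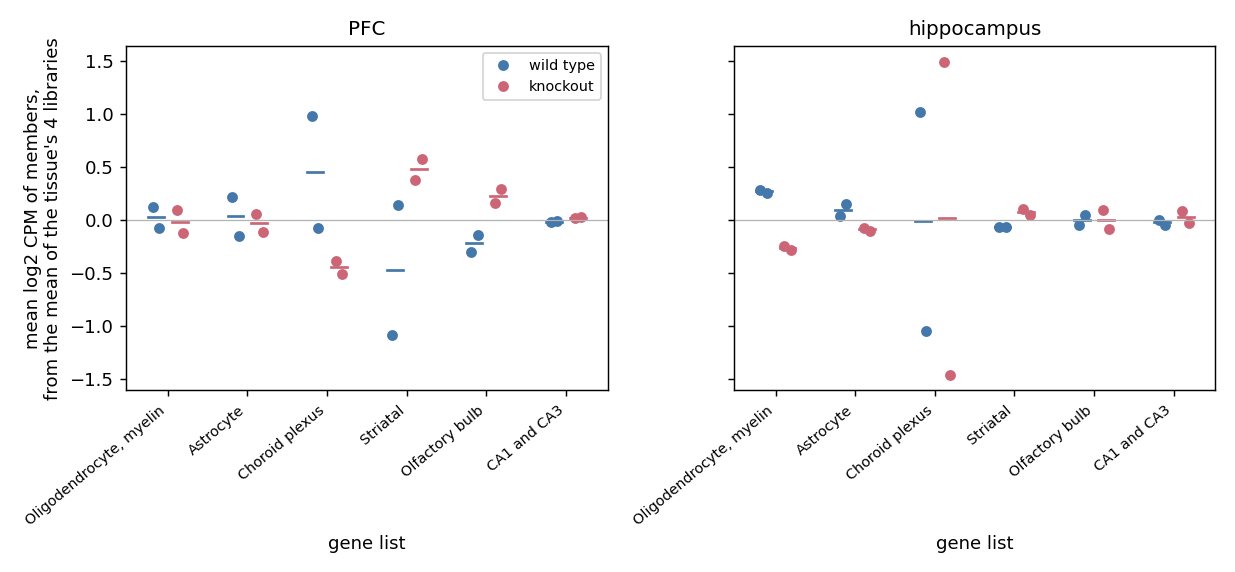
Score of 6 gene lists in each library (mean log2 CPM of the members around the mean of the tissue's 4 libraries, 1 point per library, bars at group means), wild type in blue and knockout in red. Myelin scores in hippocampus are 0.28 and 0.25 in wild type and -0.25 and -0.29 in knockouts, while the striatal scores of the 2 wild-type PFC libraries are -1.09 and 0.14.

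Of the remaining PFC lists, neurogenesis and proliferation markers were higher (median log2 fold change 0.22, adjusted p = 3.48e-05, adjusted p = 0.257 with an estimated correlation). In it 2 rose over the list alone, Calb2 and the intermediate progenitor factor Eomes at 2.34, SE 0.67. Both are also members of the olfactory bulb list, and Eomes was low, at 0.171 ± 0.163 to 0.883 ± 0.230 CPM. Dcx, a member of both lists, was 0.06, SE 0.11. Meningeal and fibroblast markers were higher (0.34, adjusted p = 4.71e-05, adjusted p = 0.972 with an estimated correlation), with the transporter Slc47a1 at 0.87. Their score was -0.76 in wild-type PFC replicate 2 against 0.20 to 0.30 in the other 3 PFC libraries. Choroid plexus markers were lower (-1.14, adjusted p = 1.21e-04, adjusted p = 0.972 with an estimated correlation), with the thyroid hormone carrier Ttr at -2.79, SE 1.31. The first member by p, Car12, went the other way at 0.53, SE 0.21. The choroid plexus score was 0.98 in wild-type replicate 1 and -0.08 in replicate 2.

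Cholesterol synthesis genes were lower in knockout PFC (-0.09, adjusted p = 0.00355, adjusted p = 0.533 with an estimated correlation), with the sterol enzymes Dhcr24 at -0.23 and Msmo1 at -0.18. Astrocyte markers were lower (-0.10, adjusted p = 0.0340, adjusted p = 0.972 with an estimated correlation). Of the first 4 by p, Slc7a10 was -0.23, the glutamate transporter Slc1a2 -0.16 and Aldoc -0.15, while Agt was higher at 0.47, SE 0.26. The astrocyte score stood apart in wild-type replicate 1, at 0.21 against -0.15 in replicate 2 and 0.05 and -0.12 in knockouts, and without that library Slc1a2 turned to 0.0170. Glucocorticoid-responsive genes were lower (-0.06, adjusted p = 0.0340, adjusted p = 0.848 with an estimated correlation), with Zbtb16 at -0.36, SE 0.10 fallen over the list alone. Immediate early genes were higher (0.08, adjusted p = 0.0340, adjusted p = 0.972 with an estimated correlation), with the synaptic scaffold gene Homer1 at 0.29. Their score was -0.06 and -0.04 in wild type, 0.24 in knockout replicate 1 and -0.14, the lowest of the 4, in knockout replicate 2. The other 32 lists were not called (adjusted p from 0.0613 to 0.934, medians from -0.27 to 0.18). In the called PFC lists 0 members passed over all genes, and adjusted over the list alone 0 passed beyond those given. Among the lists not called were PI3K-AKT-mTOR pathway genes (median 0.00), FoxO target genes (0.01) and oligodendrocyte and myelin markers (-0.04).

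Over all genes in PFC, edgeR called 0 of 17990, with 1048 genes (5.83%) at unadjusted p under 0.05, while DESeq2 called 17 and limma 0. Without wild-type PFC replicate 2 the count was 137. After Cdhr1 the genes with the smallest p were Eps8l1 at -1.68, Klhl13 at 0.81 and Stac2 at -0.42 on the log2 scale (adjusted p = 0.296 each). Then came Dpy19l3 at 0.35, Crym at 0.60, Ppp1r2 at 0.37, Ano2 at 1.08, Frmd7 at 1.98 and Lamb1 at 0.52 (adjusted p = 0.303 each). Of these, Stac2, an adaptor of calcium channels, was at 151 ± 7.59 to 113 ± 8.69 CPM. Crym, a thyroid hormone binding protein found in striatum and cortex, had 48.8 ± 11.1 to 74.2 ± 0.412 CPM.

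Averaged over both tissues, with tissue kept in the model (4 knockout against 4 wild-type libraries), Eps8l1 and Ccl28 stood lower in knockouts. The labels do not say whether both tissues came from the same animals, so the 4 libraries of a genotype may not be independent. Eps8l1 (ENSMUSG00000006154, chromosome 7 from 4460674 to 4480487), which links receptor signalling to actin, went from 14.9 ± 4.16 to 4.61 ± 0.531 CPM in PFC and from 16.9 ± 4.69 to 7.27 ± 2.80 CPM in hippocampus (log2 fold change -1.45, SE 0.19, adjusted p = 0.0710). Ccl28 (ENSMUSG00000074715, chromosome 13 from 119623819 to 119654359), an epithelial chemokine, went from 6.02 ± 0.713 to 3.17 ± 0.882 CPM in PFC and from 7.90 ± 0.320 to 3.45 ± 1.15 CPM in hippocampus (log2 fold change -1.06, SE 0.18, adjusted p = 0.181). In the authors' deposited table, which compares the genotypes over all 8 libraries, Eps8l1 had a log2 fold change of -1.41 (adjusted p = 0.00401) and Ccl28 of -1.07 (adjusted p = 0.0385). Across genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and those averaged here had a Pearson correlation of 0.896.

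**Figure D3:**
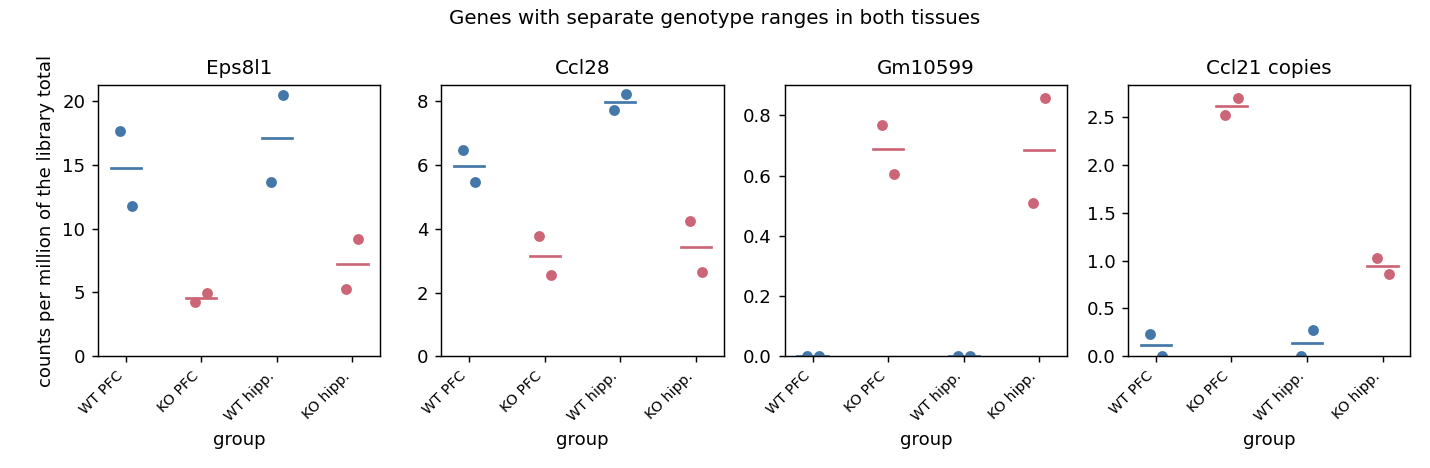
Counts scaled to the library total (CPM) of Eps8l1, Ccl28, Gm10599 and the summed Ccl21 copies in each library (1 point per library, bars at group means), wild type in blue and knockout in red. Eps8l1 counts run from 216 to 368 in wild-type and from 77 to 161 in knockout libraries.

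Gm10599 (ENSMUSG00000118458, no position found) had 0 counts in the 4 wild-type libraries and 14, 11, 9 and 15 in the knockout ones, at least 16.3-fold over the group on a floor of 3 counts. In the authors' deposited table Gm10599 had a log2 fold change of 6.09 (adjusted p = 0.00345), and the averaged fit here gave it an adjusted p of 0.181. The chemokine copies Ccl21b (chromosome 4 from 42255767 to 42256432) and Gm10591 (chromosome 4 from 42612195 to 42612860) also had 0 counts in wild type, with 61 and 62 in knockouts. These copies share 100% of their 31-base words with other Ccl21 copies, so reads cannot be assigned to a single copy, and summed over the copies the counts were 128 in knockouts and 9 in wild type.

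By edgeR the averaged comparison called 0 of 17990 genes, with 1040 genes (5.78%) at unadjusted p under 0.05, 16 by DESeq2 and 0 by limma. It called 112 without wild-type PFC replicate 2 and 18 without wild-type hippocampus replicate 1. Fa2h at -0.38 and Cdhr1 at 0.84 followed (adjusted p = 0.181 each). Next were Aspa at -0.41 and Dpy19l3 at 0.24 (adjusted p = 0.358 each). Mal at -0.36, Traip at 0.44, Cnp at -0.35 and Igfn1 at 0.75 had an adjusted p of 0.375 each.

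Of the lists, 10 were called when averaged, 4 higher and 6 lower, and 0 held with an estimated correlation or by fry. Oligodendrocyte and myelin markers were lower (median log2 fold change -0.33, adjusted p = 7.54e-39, adjusted p = 0.102 with an estimated correlation). All 23 of these genes were below 0, with 18 fallen over the list alone and 0 over all genes. In PFC alone the myelin scores overlapped between genotypes, with 0.12 and -0.08 in wild type and 0.09 and -0.13 in knockouts. Striatal markers were higher (0.44, adjusted p = 3.83e-21, adjusted p = 0.453 with an estimated correlation), with 1 risen over the list alone. The striatal score was -1.09 in wild-type PFC replicate 1 against 0.14 in replicate 2. Olfactory bulb and neuroblast markers were higher (0.22, adjusted p = 4.31e-07, adjusted p = 0.102 with an estimated correlation), with Cdhr1, Synpr and Dlx6 risen over the list alone. In hippocampus alone the olfactory bulb scores overlapped, with -0.05 and 0.05 in wild type and 0.09 and -0.09 in knockouts. All 20 astrocyte markers were below 0 (-0.13, adjusted p = 1.34e-07, adjusted p = 0.787 with an estimated correlation). In PFC alone the astrocyte scores overlapped, with 0.21 and -0.15 in wild type and 0.05 and -0.12 in knockouts. Immediate early genes were higher (0.12, adjusted p = 6.10e-05, adjusted p = 0.787 with an estimated correlation). Of these, 3 rose over the list alone, Egr3 at 0.20, SE 0.06, Egr4 at 0.31, SE 0.08 and Homer1 at 0.21, SE 0.06.

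Averaged glucocorticoid-responsive genes were lower (-0.15, adjusted p = 1.30e-04, adjusted p = 0.302 with an estimated correlation), with Arrdc2 at -0.35, SE 0.09 fallen over the list alone. Cholesterol synthesis genes were lower (-0.08, adjusted p = 1.02e-04, adjusted p = 0.302 with an estimated correlation), with Msmo1 at -0.17. Choroid plexus markers were lower (-0.40, adjusted p = 0.0373, adjusted p = 0.793 with an estimated correlation), with scores of 1.02 and -1.05 in the 2 wild-type hippocampal libraries. Ribosomal protein genes had a median of -0.03, adjusted p = 0.0429, adjusted p = 0.793 with an estimated correlation. CA1 and CA3 pyramidal markers had one of 0.03, adjusted p = 0.0398, adjusted p = 0.787 with an estimated correlation. In the averaged comparison 0 members of these lists passed over all genes, and adjusted over the list alone 0 passed beyond those given. The other 31 lists were not called (adjusted p from 0.0675 to 0.904, medians from -0.19 to 0.07).

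The genotype difference itself was compared between tissues, hippocampus minus PFC, with the myelin gene Trf at the smallest p and no gene called. On the log2 scale Trf was -0.59, SE 0.09, Ermn -0.67, Igfn1 1.91, SE 0.30 and Ypel2, a centrosome-linked protein, -0.63, with an adjusted p of 0.187 for each. Calb2 was -1.57, SE 0.29 (adjusted p = 0.418), and Fa2h and Mog were -0.66 and -0.78 (adjusted p = 0.422 each). Unc13c was -1.03, the muscarinic receptor gene Chrm3 0.47 and Carhsp1 -0.48 (adjusted p = 0.433 each). By edgeR 0 of 17990 genes were called, with 1184 genes (6.58%) at unadjusted p under 0.05, 13 by DESeq2 and 0 by limma. The count was 52 without wild-type PFC replicate 2, 17 without wild-type hippocampus replicate 1 and 9 without knockout hippocampus replicate 1. Across the 17990 genes, which are not independent replicates, the log2 fold changes of the 2 tissues had a Pearson correlation of 0.008 and shared a sign in 48.6%. The 2 contrasts share no libraries, but the labels do not say whether they share animals.

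By camera 11 lists differed between tissues, 3 toward higher and 8 toward lower values in hippocampus, and 0 held with an estimated correlation or by fry. Oligodendrocyte and myelin markers (median log2 fold change -0.55, adjusted p = 1.43e-30, adjusted p = 0.110 with an estimated correlation) had 16 fallen over the list alone. Presynaptic release genes differed upward (0.12, adjusted p = 6.17e-04, adjusted p = 0.704 with an estimated correlation). Of these, 2 rose over the list alone, Unc13b at 0.42, SE 0.09 and Stx1a at 0.63, SE 0.16, and 1 fell, Unc13c at -1.03, SE 0.21. Unc13c is a granule cell factor, and wild-type hippocampus replicate 2 carried cerebellar transcripts. Striatal markers (-0.63, adjusted p = 6.48e-10, adjusted p = 0.704 with an estimated correlation) included Ppp1r1b at -0.84, SE 0.32. Choroid plexus markers (1.54, adjusted p = 6.17e-04, adjusted p = 0.842 with an estimated correlation) included Ttr at 3.08, SE 1.70, which turned to -0.80 without knockout hippocampus replicate 1. Olfactory bulb and neuroblast markers differed downward (-0.18, adjusted p = 1.34e-09, adjusted p = 0.0950 with an estimated correlation), with 6 fallen over the list alone. Neurogenesis and proliferation markers (-0.35, adjusted p = 4.86e-09, adjusted p = 0.0955 with an estimated correlation) had 2 fallen over the list alone, and thalamic and habenular markers (-0.20, adjusted p = 0.0367, adjusted p = 0.481 with an estimated correlation) had 2. The thalamic score in hippocampus was 0.18 in wild-type replicate 2, the library with cerebellar transcripts, against 0.02, -0.03 and -0.17 in the other 3. Over all genes 0 members of any list passed. The other 30 lists were not called (adjusted p from 0.0852 to 0.732, medians from -0.25 to 0.35).

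Between the tissues of wild-type mice, hippocampus against PFC, markers of the regions led the lists. CA1 and CA3 pyramidal markers were higher in hippocampus (median log2 fold change 0.97, adjusted p = 5.13e-42, adjusted p = 0.0422 with an estimated correlation). Of 30 genes 25 rose and 3 fell over all genes, and 26 and 3 did when adjusted over the list alone. Cortical projection neuron markers were lower (median log2 fold change -1.25, adjusted p = 8.21e-17, adjusted p = 0.0422 with an estimated correlation), with 16 of 24 fallen and 6 risen by either count. Dentate gyrus markers were higher (1.12, adjusted p = 1.59e-21, adjusted p = 0.0911 with an estimated correlation), with 13 of 21 risen and 2 fallen by either count. Striatal markers were lower (-3.03, adjusted p = 1.89e-23, adjusted p = 0.372 with an estimated correlation), with 20 of 21 fallen by either count. Genes higher in hippocampus included the transcription factor Lhx9 at 5.87, SE 0.24 (adjusted p = 4.82e-09). The desmosome gene Dsp, a dentate marker, went from 1.65 ± 0.870 CPM in PFC to 53.8 ± 7.19 in hippocampus (log2 fold change 5.02, SE 0.22, adjusted p = 7.89e-09). The mossy fibre synapse organiser C1ql2 went from 1.40 ± 0.122 to 41.0 ± 10.2 CPM (log2 fold change 4.86, SE 0.21, adjusted p = 5.80e-09).

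In this comparison edgeR called 4373 of 17990 genes, 2156 higher and 2217 lower in hippocampus, with 6266 genes (34.8%) at unadjusted p under 0.05, and 2913 without wild-type hippocampus replicate 1. The other leading genes on the higher side were Fat2 5.98 (adjusted p = 0.00543), Krt2 5.68 (adjusted p = 3.29e-07), Slc9a4 5.60 (adjusted p = 2.70e-08), Rtl3 5.30 (adjusted p = 4.70e-06) and Cd109 4.72 (adjusted p = 2.45e-07). The cerebellar gene Fat2 had 12 counts in wild-type hippocampus replicate 1 and 779 in replicate 2. On the lower side were Sh3rf2 -7.45 (adjusted p = 2.58e-05), Cd4 -6.96 (adjusted p = 1.50e-05), Mdfic2 -6.80 (adjusted p = 7.87e-06), and Serpina9 -5.51 (adjusted p = 2.71e-04). They were followed by Olfr78 -5.23 (adjusted p = 1.78e-05), Trbc2 -5.15 (adjusted p = 1.84e-05), Ighg2c -5.09 (adjusted p = 1.35e-04) and Chat -4.70 (adjusted p = 5.16e-05). Sh3rf2 and Serpina9 belong to the striatal list, whose score was low in wild-type PFC replicate 1.

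Of the 41 lists, 13 were called between tissues and 2 held with an estimated correlation, the CA1 and CA3 and the cortical lists, while fry called 14.

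Presynaptic release genes were lower in hippocampus (-0.34, adjusted p = 3.84e-05, adjusted p = 0.565 with an estimated correlation), with 18 of 30 fallen over all genes and 20 when adjusted over the list alone, and 3 risen by either count. Circadian clock output genes were lower (-0.44, adjusted p = 4.07e-07, adjusted p = 0.362 with an estimated correlation), with 13 of 18 fallen over all genes and 13 when adjusted over the list alone, and 1 risen by either count. Neuropeptide genes were lower (-0.21, adjusted p = 0.0151, adjusted p = 0.362 with an estimated correlation), with 9 of 21 fallen over all genes and 9 when adjusted over the list alone, and 4 risen by either count. Endothelial markers were lower (-0.37, adjusted p = 0.00165, adjusted p = 0.721 with an estimated correlation), with 12 of 20 fallen over all genes and 14 when adjusted over the list alone. Cholesterol synthesis genes were lower (-0.22, adjusted p = 0.0110, adjusted p = 0.386 with an estimated correlation), with 9 of 22 fallen over all genes and 12 when adjusted over the list alone. Transcripts of the mitochondrial genome were lower (-0.37, adjusted p = 0.0130, adjusted p = 0.833 with an estimated correlation), with 8 of 12 fallen over all genes and 9 when adjusted over the list alone. In wild-type mice choroid plexus markers were higher (1.74, adjusted p = 0.0213, adjusted p = 0.833 with an estimated correlation), with 6 of 22 risen over all genes and 6 when adjusted over the list alone, and scores of 1.02 and -1.05 in the 2 wild-type hippocampal libraries. Ependymal and cilia markers were higher (1.07, adjusted p = 0.00187, adjusted p = 0.575 with an estimated correlation), with 8 of 16 risen over all genes and 8 when adjusted over the list alone. Meningeal and fibroblast markers were higher (0.56, adjusted p = 0.00187, adjusted p = 0.833 with an estimated correlation), with 6 of 20 risen over all genes and 10 when adjusted over the list alone. The other 28 lists were not called (adjusted p from 0.0587 to 0.991, medians from -0.36 to 0.44). Pten was -0.33 (SE 0.07, 95% confidence interval -0.48 to -0.19, adjusted p = 0.00244) on the log2 scale, lower in hippocampus than in PFC.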

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

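Of the tests weighed here, only the removal of a trend with GC content, length and expression was planned before the values were seen, and all the others were chosen after. The rule that a median must pass its bound by more than the SD of the members was also set after the values were seen. It changed the reading of 1 test, the one without wild-type PFC replicate 1. That SD shows how unlike the members are and does not measure the spread between libraries. Where a library is left out, its group rests on 1 library. The differences between tissues given next were called by camera with a preset correlation.

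The genotype difference between tissues, hippocampus minus PFC on the log2 scale, had a median of -0.55 (adjusted p = 0.110 with an estimated correlation) for oligodendrocyte and myelin markers, -0.27 (adjusted p = 0.768 with an estimated correlation) for oligodendrocyte precursor markers, -0.63 (adjusted p = 0.704 with an estimated correlation) for striatal markers, -0.18 (adjusted p = 0.0950 with an estimated correlation) for olfactory bulb and neuroblast markers (mean -0.88) and -0.35 (adjusted p = 0.0955 with an estimated correlation) for neurogenesis and proliferation markers. It was -0.58 (adjusted p = 0.704 with an estimated correlation) for meningeal and fibroblast, -0.44 (adjusted p = 0.615 with an estimated correlation) for ependymal and cilia, and -0.20 (adjusted p = 0.481 with an estimated correlation) for thalamic and habenular markers. On the higher side it was 1.54 (adjusted p = 0.842 with an estimated correlation) for choroid plexus markers, 0.12 (adjusted p = 0.704 with an estimated correlation) for presynaptic release genes and 0.12 (adjusted p = 0.615 with an estimated correlation) for cortical projection neuron markers. Choroid plexus scores were 1.02 and -1.05 in wild-type and 1.49 and -1.46 in knockout hippocampus.

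Myelin genes in hippocampus: the loss of PTENδ may lower myelin gene expression, or the knockout pieces may hold less white matter. A trend with GC content, length and expression is excluded, since the median of the list was -0.63 (SD 0.21 over 23 genes) after its removal. Cerebellar tissue in wild-type replicate 2 is excluded as the sole source, since the median without that library was -0.53 (SD 0.19). A smaller share of oligodendrocyte-rich tissue stays open. It would lower the members by a like amount, but a genotype effect could do so too, so the spread of the members cannot decide between them. Over the 22 members outside the precursor list the SD of the fold changes was 1.47 times their mean SE. Their falls were not all alike, with Myrf at -0.28, SE 0.07 and Mog at -0.74, SE 0.11. In hippocampus the myelin scores of the 2 libraries of a group differed by 0.03 in wild type and 0.04 in knockouts, against -0.53 between genotypes.

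Striatal genes in PFC: more striatal tissue in the knockout pieces could give the higher striatal genes, and so could a genotype effect. A share of striatal tissue that differs between pieces whatever the genotype stays open, since the scores of the 2 wild-type libraries differed by 1.22 and those of the genotypes by 0.95. Wild-type replicate 1 as the sole source cannot be told apart from a genotype difference, since the median without it was 0.32 (SD 0.17). A trend with GC content, length and expression is excluded, with a median of 0.82 (SD 0.22) after its removal.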

How the results depend on the processing

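Counts of called genes moved with the settings, and the cause was not tested. In PFC (0 by edgeR) they were 222 with no filter, 94 with the replicate block, 1 with a robust prior, 17 by DESeq2 and 1 at an adjusted p under 0.1. In hippocampus (6) they were 162 with no filter, 53 with the block, 3 with a robust prior, 18 by DESeq2, 0 by limma with either pseudocount, 16 with hippocampus fitted alone and 1 at an absolute log2 fold change of at least 1. Averaged (0) they were 223 with no filter, 69 with the block, 16 by DESeq2 and 1 at an adjusted p under 0.1. For the difference between tissues (0) they were 197 with no filter, 41 with the block and 13 by DESeq2, and between tissues in wild type (4373) 1270 at an absolute log2 fold change of at least 1. Called lists with an estimated correlation and by fry were 1 and 0 in PFC (9 by camera), 0 and 0 in hippocampus (15), 0 and 0 averaged (10), and 0 and 0 for the difference (11). The correlation across genes between the tissues' fold changes (0.008) was -0.0256 at an average log2 CPM of at least 4 and -0.0295 with a prior count of 5.

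With each library left out in turn, called genes ran from 0 to 137 in PFC, 0 to 42 in hippocampus, 0 to 112 averaged, 0 to 52 for the difference and 2913 to 4359 between tissues. Called lists ran from 8 to 17 in PFC, 11 to 17 in hippocampus, 7 to 15 averaged and 9 to 16 for the difference. Adjusted over the list alone, counts ran from 18 to 22 for myelin genes in hippocampus, 0 to 21 for striatal and 6 to 10 for olfactory bulb genes in PFC, and the correlation across genes from -0.0209 to 0.0286. Log2 fold changes ran from -0.0156 to 0.15 for Pten in PFC, 0.02 to 0.09 for Pten in hippocampus, -1.62 to 1.29 for Enpp2 in hippocampus (0.05), -0.33 to 0.0170 for Slc1a2 in PFC (-0.16) and -0.80 to 5.86 for the tissue difference of Ttr. Pten in PFC was -0.0156 without wild-type replicate 2, Slc1a2 0.0170 without wild-type PFC replicate 1, and Ttr -0.80 without knockout hippocampus replicate 1. Enpp2 was -0.61 without wild-type hippocampus replicate 2, -1.62 without knockout replicate 1, -0.10 with the block, and -0.13 and -0.14 by limma. Over all settings the 6 hippocampal genes kept their call in 67 cases, lost it in 41 and reversed in 0. In the lost cases the log2 fold changes of the myelin genes among them ran from -0.76 to -0.43, and those of Igfn1 from 0.64 to 1.86.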

Other observations

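The tests named here on the genes shared by both tissues were chosen after the values were seen, and the counts over other splits of the libraries were planned before. Eps8l1, Ccl28, Gm10599 and the Ccl21 copies separate the genotypes in PFC and in hippocampus alike, and this may come from the altered allele or from another genomic difference between the mice of the 2 genotypes, which was not tested. Of Eps8l1, Ccl28, Ccl21b and Gm10591, 0 of 4 lie within 5 Mb of Pten, so they do not themselves lie in DNA carried along next to it. Their positions cannot show whether such DNA acts on genes elsewhere, so that stays open. Gm10599 has no position and stays open too. The sum over the 4 Ccl21 copies in the count table was 14.4 times as high in knockouts (95% confidence interval 7.35 to 32.2, which covers counting error only), with 15 to 49 counts in each knockout and 0 to 5 in each wild-type library. A move of reads among these 4 copies does not give that sum, but a 5th copy, Gm21541, is not in the count table, so for the Ccl21 copies reads assigned to another copy cannot be told apart from a genotype difference.

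Igfn1, the gene that rose in knockout hippocampus, had 52 and 62 counts in wild-type and 124 and 230 in knockout hippocampus, and a mean of 52.0 CPM in wild-type PFC. The 49 genes enriched in PFC had a median of 0.35 on the log2 scale in knockout hippocampus replicate 2, against -0.15, -0.05 and -0.11 in the other 3 hippocampal libraries, so Igfn1 could partly follow cortical tissue in that piece.

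The libraries were also divided into every 4 against 4 split, with tissue kept in the model, and this was planned before the values were seen. Because edgeR called 0 genes for genotype, all 34 splits that could be fitted have at least as many, so the count of genes says nothing on chance. At the same threshold 15 of the 34 called 1 or more genes. Some of the 34 divide the libraries of a tissue unevenly, unlike genotype. Among those that divide both tissues evenly the highest called 46 genes. That split divides the hippocampus by genotype and the PFC by replicate number. Of the even splits that mix the genotypes in both tissues the highest called 17 genes. It divides both tissues by replicate number, which points to some structure of the samples, whose nature was not tested. For lists, 25 of 34 splits called at least as many as genotype did (10), with uneven splits and those that divide 1 tissue by genotype included. The highest even split called 18 lists, but it divides the hippocampus by genotype. Of the even splits that mix the genotypes in both tissues the highest called 17 lists, so chance division of the libraries is not excluded.

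In wild-type hippocampus replicate 2, cerebellar genes chosen after the values were seen had 688 counts for Gabra6, 1091 for Cbln1 and 1326 for Car8, against 2, 215 and 119 in replicate 1. Crtam had 89 counts in that library and 2 or fewer in every other. Ttr had 17704 and 1359 counts in wild-type and 21271 and 743 in knockout hippocampus. Entpd4b had 100 counts in knockout PFC replicate 2 and 7 or fewer in each other library. Nnt had 5 to 11 counts in each of the 8 libraries. Xist had 1 to 9 counts and Ddx3y 576 to 1011 in all 8 libraries. No p-value was given for 21 genes of the authors' deposited table.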
